A study of Mus musculus with 12 samples.

How the data were processed

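Lung RNA from 12 C57BL/6 mice was profiled by quantitative PCR on TaqMan OpenArray plates, in which each microRNA assay is a nanolitre reaction. Per the labels, 100 ng of RNA was reverse transcribed with Megaplex primer pools A and B and pre-amplified for 12 cycles before the arrays were run on a QuantStudio instrument. The table of threshold cycles was deposited by the authors as relative threshold cycles (Crt), a log2 scale that runs downward, since a reaction with more template crosses the threshold earlier. A difference of 1 cycle was read as a difference of 1 on the log2 scale, which assumes that the template doubled in each cycle; the efficiency of each assay is not given in the sources used here. The second deposited table holds values by the authors on the same log2 scale, forced to nearly the same distribution in all 12 mice, as quantile normalization does. How Crt was called, and how repeated reactions were combined, is not given in the sources used here.

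The Crt table names assays by position and the normalized table names the microRNAs, so the names were carried over by matching the rank of each assay within every mouse. Of 762 assays, 326 gave a Crt in at least 1 mouse, and 322 of them were matched, each the best match in both directions. The largest mean rank difference of a match was 0.0072, and the next best candidate was at least 2.51 times farther away. The other 4 assays, with 40 values, had no name and were left out. Because ranks made the match, the identical order of both tables is no separate check of the names. Of 9144 reactions, 3839 had a Crt, from 9.61 to 31.74. The normalized table lists 383 assays in pool A and 379 in pool B. Every column was assigned to a mouse by the labels. OpenArray reactions carry no read depth, so their number and the Crt limit set the precision.

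A microRNA was taken as detected in a mouse at a Crt below 28. Each mouse's mean Crt over the 260 microRNA assays detected in all 12 mice (the global mean) was subtracted, and the sign was turned so that a higher value means more RNA. The 296 assays detected in at least 2 of 3 mice of each of the 4 groups were tested, 181 in pool A and 115 in pool B. An undetected reaction was treated as missing, which applied to 36 of these assays. Control RNAs (10 assays detected in all mice) were kept out of the tests and of the global mean. In total, 11 names had more than 1 assay, and these are told apart by their assay number in parentheses; a # after a name marks the other arm of the hairpin, as in the assay names.

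All 12 mice entered a single limma fit of 4 group means, with 8 residual degrees of freedom and 2.41 prior ones. P values were adjusted by the method of Benjamini and Hochberg over the 296 assays in each comparison, and an assay was called at an adjusted p under 0.05. The comparisons were radiation against none in each diet, flaxseed against control diet with and without radiation, both treatments against neither, radiation and flaxseed each pooled over the other factor, and the interaction of diet with radiation. The named microRNAs are up to 10 higher and 10 lower calls with the largest difference in each comparison. Where fewer than 5 were called, the 5 with the smallest unadjusted p were added. The rule also takes 2 to 4 members of each list and 16 fixed microRNAs: miR-34a, miR-34c, miR-150, miR-21, miR-155, miR-146a, miR-142-3p, miR-223, miR-451, miR-126-3p, miR-29c, miR-200c, miR-145, miR-210, miR-1 and let-7b. These choices were made before the data were examined.

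Lists of microRNAs linked to p53, inflammation, fibrosis, and oxygen and stress were fixed with them. So were the let-7 family, the miR-17 to miR-92 clusters, the miR-29 family, the miR-30 family, the Dlk1-Dio3 locus, and markers of myeloid, lymphoid, epithelial, ciliated, striated muscle, erythroid, endothelial, smooth muscle and liver cells. A list with at least 3 tested members was tested with limma's cameraPR at a preset correlation of 0.01, and with camera at an estimated correlation. Detected assays per mouse were compared by exact two-sided permutation tests. The correlation of effects across assays was set against the same value in other splits of the mice.

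Alternatives were quantile normalization, scaling to the control RNAs, to the median assay or within each primer pool, no normalization, and the authors' normalized values. Further ones were Crt limits of 26, 30 and none, assays detected in all 12 mice, undetected reactions set to 28, a fit of the compared groups alone, array weights, a trended robust fit, an adjusted p under 0.10, and leaving out each mouse in turn. Chosen after seeing the data were fits without mice 2 and 11, fits without the 3 unirradiated flaxseed mice, and the comparison of unirradiated flaxseed with irradiated control mice.

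The fit was tested on simulated data in 20 simulations with 20 of 296 assays changed at each size. Shifts of 2 on the log2 scale were recovered in 79.2% to 85.5% of cases in the comparisons of 3 mice with 3, and in 61.5% for the interaction. Shifts of 1 were recovered in 36.8% to 46% and in 12% of cases. Between 3.8% and 8.7% of calls were false. The simulated noise was normal, independent between assays, with the same spread in every group and no late reactions. In the data the median SD of the assays ran from 0.208 to 0.393 between groups, so these rates may not carry over. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.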

Results

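The data address which lung microRNAs respond to dietary flaxseed, to radiation, and to both. MicroRNA levels were measured in the lungs of 12 C57BL/6 mice in 4 groups of 3. Mice ate a control diet or a diet with 10% flaxseed for 21 days, and 1 group on each diet received 13.5 Gy of radiation, with lungs taken 48 h later. The unirradiated control group held mice 2, 4 and 5, the irradiated control group mice 7, 8 and 9, the unirradiated flaxseed group mice 11, 12 and 13, and the irradiated flaxseed group mice 15, 17 and 18. Values are threshold cycles relative to the mean of 260 microRNAs in the same mouse, on the log2 scale, and differences are given with their standard error (SE).

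The number of detected microRNA assays was 309 ± 1.2 (SD, n = 3) in unirradiated control mice, 308 ± 1.2 in irradiated control mice, 289.7 ± 8.1 in unirradiated flaxseed mice and 311 ± 0.6 in irradiated flaxseed mice. The mean threshold cycle was 19.95 ± 0.12 in unirradiated control mice, 19.75 ± 0.01 in irradiated control mice, 20.56 ± 0.58 in unirradiated flaxseed mice and 19.69 ± 0.27 in irradiated flaxseed mice (SD, n = 3 each), and mouse 13 stood at 21.2. Mouse 11 had a gap between primer pools B and A of 1.78 cycles, against 2.37 to 2.81 in the other 11 mice. Between 40.3% and 49.1% of the values carried a 4th decimal in unirradiated control and irradiated flaxseed mice, and 0% did in the other 6 mice, as if the former were means of 2 readings. This split is the same as the interaction of diet with radiation and lies across each comparison of 2 groups that differ in 1 factor, so none of these is free of it, whereas the effects pooled over the other factor are balanced for it. The Spearman correlation of levels between mice ranged from 0.877 to 0.994.

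Flaxseed was compared with control diet over both radiation states, 6 mice against 6. miR-34a, a direct target of p53, rose by 0.99 ± 0.12 (SE), or 1.99-fold, and was higher in all 6 flaxseed mice than in any of the 6 control mice. miR-150, which is abundant in mature lymphocytes, fell by 1.33 ± 0.21 on the log2 scale, and miR-142-3p, a microRNA of blood-forming cells, fell by 1.77 ± 0.42. miR-503, a relative of miR-16, fell by 0.94 ± 0.14. Its fall was larger in irradiated mice, where it was called, than in unirradiated mice, where it was not. The interaction of -1.31 was itself called, so the pooled value of miR-503 averages unlike differences in the radiation states. miR-375, found in epithelial and endocrine cells, rose by 0.62 ± 0.14. miR-21, which is raised in inflamed and fibrotic tissue, fell by 1.05 ± 0.27, with -2.53 ± 0.41 in unirradiated mice, where it was undetected in mouse 11, and 0.44 ± 0.36 in irradiated mice.

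The limma adjusted p was 0.00192 for miR-34a, 0.0059 for miR-150, 0.0364 for miR-142-3p, 0.00504 for miR-503, 0.0443 for miR-21 and 0.0259 for miR-375. In all, 31 assays were called, 18 higher and 13 lower, with differences from 0.43 to 1.65 and from -0.58 to -2.56, and 88 passed at an unadjusted p under 0.05. The other largest increases were in miR-296 (1.65), miR-1937C (1.09), miR-1937B (1.00), miR-335 (0.95), miR-1 by assay 002222A (0.92), miR-26b# (0.88), miR-135b (0.83), miR-421 (0.81) and miR-376c (0.72). The other largest decreases were in miR-124a (-2.56), miR-423-5p (-2.01), miR-467a (-1.68), miR-25 (-1.67), miR-1839-3P (-1.51), miR-1198 (-0.70) and miR-213 (-0.68). Of these, miR-124a, miR-423-5p, miR-467a and miR-25 were among the 19 pool A assays that fell in unirradiated mice, weighed below. miR-26b#, miR-421, miR-467a and miR-25 were also called for the interaction (-2.36, 1.23, 3.14 and 4.61). Their pooled values thus average unlike differences in the 2 radiation states. In unirradiated mice miR-26b# was at 2.06, miR-467a at -3.25 and miR-25 at -3.98. Of the 19 assays of the 16 fixed microRNAs, 3 rose and 3 fell, and the other 13 ranged from -2.31 to 1.08. The 2 assays of miR-200c did not move alike, with 0.69 by assay 000505B and -0.15 by assay 002300A. Among the 31 calls, 58.1% were increases, against 14.3% when scaled to the control RNAs, 6.2% with no normalization and 71% when scaled to the median assay, and these scalings moved the median of all assays from 0.05 to -0.18, -0.23 and 0.16. miR-150, miR-503 and miR-124a stayed called under all alternatives tried, and miR-34a under all but 1, no normalization, where it was 0.72 with an adjusted p of 0.13 in a range from 0.000566 to 0.13. miR-21 ranged from -2.82 to -0.91 over 26 alternatives and lost its call in 10 (adjusted p from 0.0176 to 0.295), among them the fits without mouse 4, 5, 8, 9, 12, 15 or 18, and miR-142-3p in 8 of 27 (0.00318 to 0.0791), those without mouse 4, 7, 8, 9, 12, 15, 17 or 18. The count was 9 without mouse 4, 16 without mouse 5, 20 without mouse 7, 9 without mouse 8, 8 without mouse 9, 9 without mouse 12, 49 without mouse 13, 7 without mouse 15, 20 without mouse 17 and 6 without mouse 18.

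**Figure D1:**
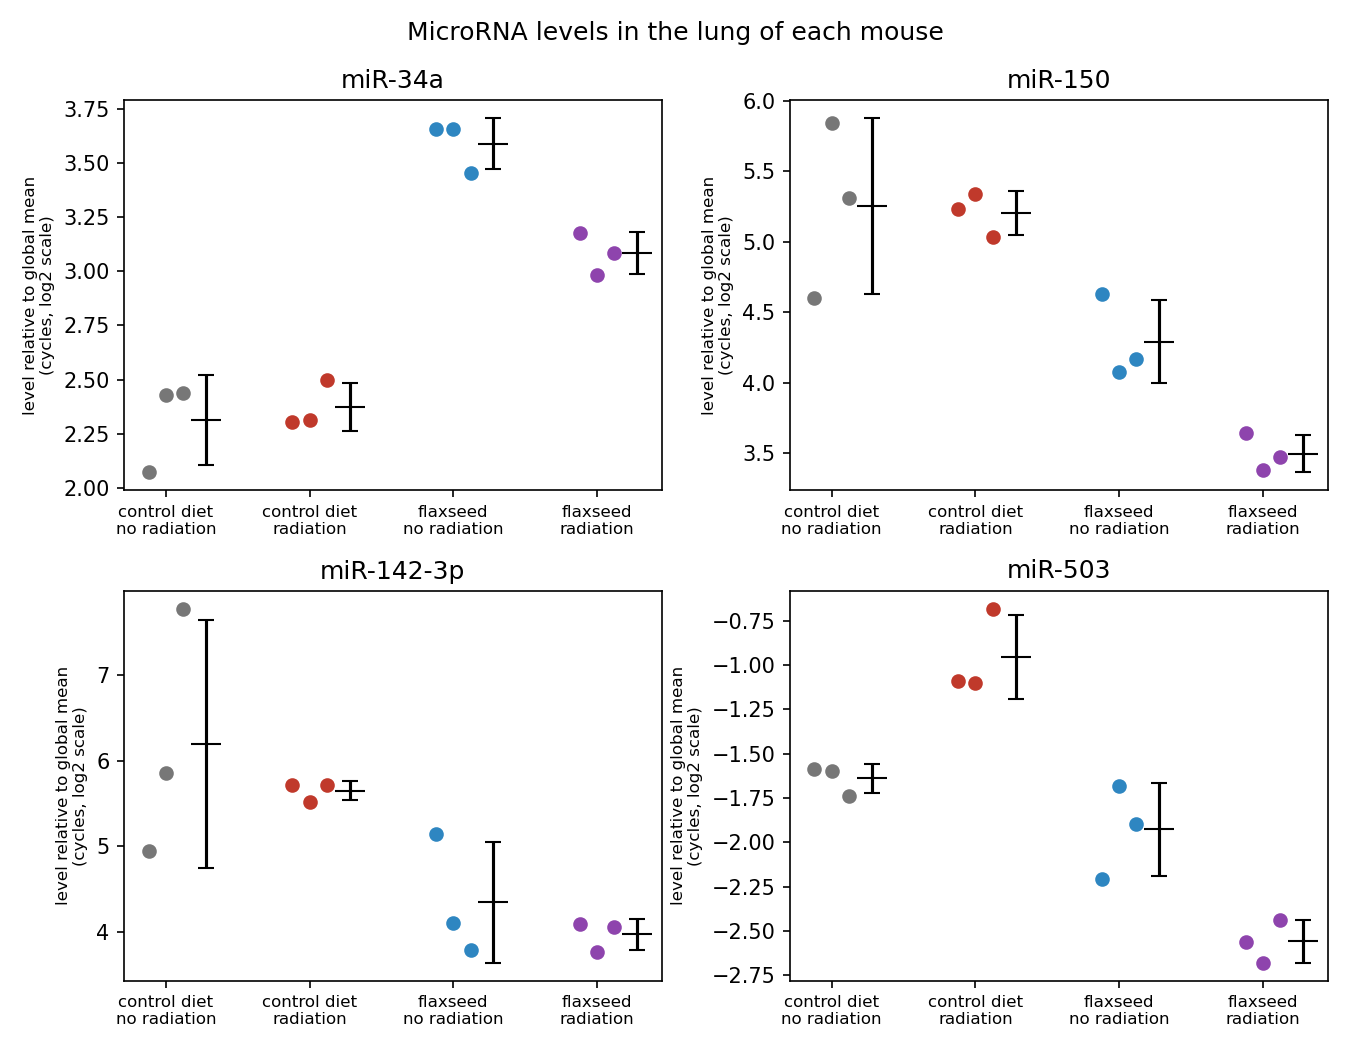
Level of miR-34a, miR-150, miR-142-3p and miR-503 relative to the global mean (cycles, log2 scale) in each mouse of the 4 groups, with points for mice and bars for the group mean ± SD (n = 3). The mean of miR-34a is 2.31 and 2.37 in the control diet groups and 3.59 and 3.08 in the flaxseed groups, while that of miR-150 is 5.25 and 5.20 against 4.29 and 3.50.

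The fixed lists describe the same pooled comparison by theme. Of 10 tested p53-linked microRNAs, miR-34a, miR-34b-3p (0.43 ± 0.12) and miR-192 (0.44 ± 0.12) rose and none fell, and 4 rose and 1 fell (miR-34c, -1.33 ± 0.39) when adjusted over the list alone. Of 4 lymphoid markers, miR-150 and miR-342-3p (-0.58 ± 0.16) fell, while miR-155 was at -1.62 ± 1.67 and miR-181a at 0.00 ± 0.23. Of 3 myeloid markers miR-142-3p fell, miR-142-5p was at -1.32 ± 0.43 and miR-223 by assay 000526B at 0.75 ± 0.33; adjusted over the list alone, 1 rose and 2 fell. Of 7 epithelial markers, miR-375 and miR-200c by assay 000505B rose, and of 4 markers of ciliated cells miR-34b-3p rose. Of 3 striated muscle markers miR-1 rose by assay 002222A (0.92 ± 0.26), and its assay 002064A gave 1.08 without a call. In the Dlk1-Dio3 locus, miR-410 (0.58 ± 0.15) and miR-376c (0.72 ± 0.20) rose of 11 tested, and in the miR-17 to miR-92 clusters miR-25 fell of 11. miR-21 was the member that fell in both the inflammation list (9 tested) and the fibrosis list (8 tested). No member was called in the let-7 family (8 tested), the miR-29 family (3), the miR-30 family (7) or the oxygen and stress list (7), although 3 of the miR-30 family rose when adjusted over the list alone. The erythroid list had 1 tested member, the endothelial and smooth muscle lists had 2 each, and the liver list had 0, with none called here. As whole lists, 0 of 98 tests passed with limma's cameraPR over 14 lists and 7 comparisons, with 25 at an unadjusted p under 0.05, the smallest adjusted p was 0.109, and the smallest with an estimated correlation was 0.393. The number that passed was above 0 in some alternatives, which are given with the processing below.

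In irradiated mice, flaxseed was compared with control diet, 3 against 3. miR-150 fell by 1.71 ± 0.29 on the log2 scale (5.20 ± 0.16 to 3.50 ± 0.13, SD), and miR-342-3p, also abundant in lymphocytes, fell by 1.15 ± 0.23. miR-503 fell by 1.60 ± 0.19, miR-20b, of the miR-17 family, fell by 1.28 ± 0.27 and miR-1903 fell by 2.31 ± 0.42. miR-421 rose by 1.43 ± 0.20, miR-30a-3p by 1.22 ± 0.25, and miR-34a by 0.71 ± 0.17. miR-1, which is abundant in heart and skeletal muscle, rose by 1.73 ± 0.36 by assay 002222A.

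The other calls were miR-1198 (-1.17), miR-130b (-1.05), miR-672 (-0.97), miR-339-5p (0.83), miR-200c by assay 000505B (1.19) and miR-381 by assay 000571A (2.73). The second assays of miR-200c, miR-381 and miR-1 gave -0.24, -0.66 and 0.90 (limma adjusted p = 0.402 for miR-1), none called. By limma, 15 assays were called, 7 higher and 8 lower, with 64 at an unadjusted p under 0.05, and adjusted p ran from 0.00199 for miR-503 to 0.0333 for miR-34a. Among the lists, 2 of 4 lymphoid markers and 1 of 11 in the miR-17 to miR-92 clusters fell. Members that rose were 1 of 10 p53-linked, 1 of 7 in the miR-30 family and 1 of 7 epithelial markers. Of 3 striated muscle markers 1 rose (miR-1, by 1 of its 2 assays). The miR-30 family list also holds 3p arms, and its member here was miR-30a-3p. The count was 4 when scaled to the control RNAs, 1 with no normalization, 72 with array weights, 48 in a fit of these groups alone, 32 without mice 2 and 11 and 26 without the 3 unirradiated flaxseed mice. It was 3 without mouse 7, 2 without mouse 8, 7 without mouse 9, 25 without mouse 11, 7 without mouse 15, 6 without mouse 17 and 7 without mouse 18.

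In unirradiated mice, flaxseed was compared with control diet, 3 against 3. miR-34a rose by 1.28 ± 0.17, from 2.31 ± 0.21 to 3.59 ± 0.12 (SD). The assays that fell most were let-7e (-6.54 ± 1.41), miR-29c (-6.08 ± 1.31), a repressor of collagen genes, miR-19a (-5.27 ± 1.22) and miR-24 (-4.34 ± 1.12). Without mouse 11 these 4 were at -4.39, -4.14, -3.41 and -2.66, all still called. In a fit of these groups alone all 4 lost their call, and so did miR-19a without mouse 4 and miR-24 without mouse 2, 4 or 5 (adjusted p up to 0.157 over 28 alternatives). miR-25 fell by 3.98 ± 0.55, miR-34c, a microRNA of ciliated cells, fell by 3.14 ± 0.58, and miR-21 fell by 2.53 ± 0.41, with miR-34c and miR-21 undetected in mouse 11. With undetected reactions set to 28, miR-21 was at -6.07 ± 2.28 without a call (limma adjusted p = 0.126, in a range from 0.00174 to 0.126) and miR-34c at -5.22 ± 1.42. miR-34c lost its call with no Crt limit (-6.26), with the authors' normalized values (-4.75) and without mouse 12 (-2.37), in a range of adjusted p from 0.00174 to 0.0704. Outside miR-34a, the increases included miR-26b# (2.06 ± 0.32), miR-449b (1.76 ± 0.43), miR-410 (1.33 ± 0.22) and miR-375 (0.95 ± 0.19).

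Further large decreases were in miR-124a (-3.30), miR-195 (-3.25), miR-467a (-3.25), miR-193b (-3.19), miR-125a-5p (-3.15) and miR-423-5p (-3.09), and further increases in miR-1937B (1.25), miR-376c (1.12), miR-335 (1.07), miR-33a# (1.00) and miR-345-5p (1.00). miR-150 was at -0.96 ± 0.29 and miR-142-3p at -1.85, neither of which passed (limma adjusted p = 0.0565 and 0.0652). By limma, 36 assays were called, 15 higher and 21 lower, with 86 at an unadjusted p under 0.05. Of the 21 lower calls, 19 were in primer pool A, and relative to the mean of unirradiated control mice those 19 had a median of -5.11 in mouse 11, -2.83 in mouse 12 and -2.17 in mouse 13. By list, 3 p53-linked microRNAs rose and miR-34c fell of 10, 2 of 4 ciliated markers rose (miR-34b-3p, 0.85, and miR-449b) and miR-34c fell, 3 of 7 oxygen and stress microRNAs fell (miR-28, miR-93 and miR-24), 2 of 8 in the let-7 family fell (let-7e and let-7c), and 3 of 11 in the miR-17 to miR-92 clusters fell. Of 7 epithelial markers, miR-375 rose and miR-429 (-2.54) fell. In the inflammation list 2 of 9 fell, in the fibrosis list 2 of 8, in the miR-29 family 1 of 3, and in the Dlk1-Dio3 locus 2 of 11 rose. The share of increases was 41.7%, against 13.3% when scaled to the control RNAs, 3.4% with no normalization and 66.7% when scaled to the median assay, with 60 calls in the last, and the median of all assays moved from 0.22 to -0.17, -0.37 and 0.46. The count was 20 without mouse 4, 9 in a fit of these groups alone and 18 with array weights.

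**Figure D2:**
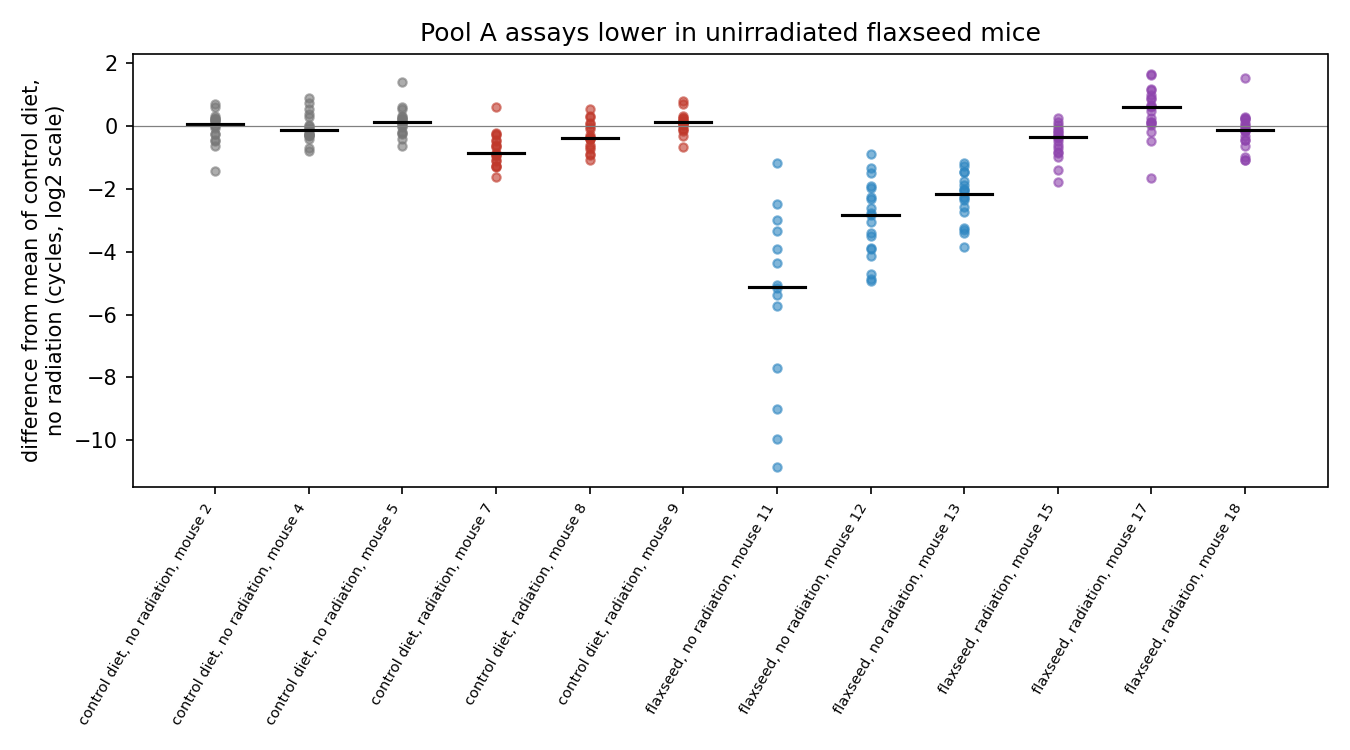
Difference of the 19 pool A assays called lower in unirradiated flaxseed mice from the mean of the unirradiated control mice (cycles, log2 scale) in each of the 12 mice, with points for assays and a bar for the median. The medians of mice 11, 12 and 13 are -5.11, -2.83 and -2.17, and the points of mouse 11 reach -10.84.

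Radiation was compared with no radiation among flaxseed mice, 3 against 3. The largest increases were miR-29c (7.16 ± 1.31), let-7e (6.91 ± 1.41), miR-19a (4.97 ± 1.22), miR-29b (4.83 ± 1.20), miR-24 (4.67 ± 1.12) and miR-25 (4.13 ± 0.55). Then came miR-30b (3.76), miR-34c (3.42), miR-195 (3.27) and miR-23b (3.20), and miR-21 rose by 2.14 ± 0.41. Without mouse 11, miR-29c, let-7e, miR-19a, miR-29b and miR-24 were at 5.23, 4.75, 3.11, 3.05 and 2.99, all still called. Of 28 alternatives miR-19a, miR-29b and miR-24 each lost the call in 4, namely without mouse 15, 17 or 18 and in a fit of these groups alone (adjusted p up to 0.0976), and let-7e in 2, one of them without mouse 17. Of the 25 increases, 19 were assays that fell in unirradiated flaxseed mice against control mice, where 1.77 were expected if the calls were independent, but both comparisons share the unirradiated flaxseed mice. The largest decreases were miR-449b (-1.44 ± 0.43), miR-455 by assay 002455A (-1.38 ± 0.29), miR-466a-3p (-1.28), miR-184 (-1.24), miR-672 (-1.15), miR-410 (-1.11), miR-20b (-1.10), miR-214 by assay 002306A (-1.03), miR-342-3p (-0.93) and miR-532-3p (-0.87), which lost their call in 4 to 19 of 28 alternatives, each in the fit without mouse 17. miR-34a was at -0.51 and miR-150 at -0.80 without a call.

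By limma, 43 assays were called, 25 higher and 18 lower, with 96 at an unadjusted p under 0.05, and 40 of the 43 were in pool A. The smallest adjusted p was 0.00777 for miR-25. By list, 4 of 7 oxygen and stress microRNAs rose, among them miR-28 (2.73) and miR-365 (1.20), 2 of 3 in the miR-29 family rose, 2 of 8 in the let-7 family rose, and miR-126# was the 1 of 2 endothelial markers that rose. Of 10 p53-linked microRNAs 1 rose and 2 fell, in the Dlk1-Dio3 locus 2 fell of 11, and of 8 fibrosis-linked ones 3 rose and 1 fell. In the miR-17 to miR-92 clusters 3 rose and 1 fell (miR-20b) of 11, in the inflammation list 2 of 9 rose, in the miR-30 family 1 of 7 rose, and of 4 lymphoid markers miR-342-3p fell. Of 7 epithelial markers miR-429 (2.66) rose, and miR-375 (-0.87) and miR-200b by assay 002251A (-0.65) fell. Of 4 ciliated markers miR-34c rose, and miR-34b-3p (-0.72) and miR-449b fell. The count was 20 when scaled to the control RNAs, 65 with no Crt limit, 0 in a fit of these groups alone, 28 without mouse 8, 14 without mouse 15, 9 without mouse 17 and 13 without mouse 18. The share of increases was 58.1%, against 95% when scaled to the control RNAs, 100% with no normalization, 72.7% with quantile normalization and 46.9% when scaled to the median assay, with a median of all assays of -0.25, -0.04, 0.61, -0.14 and -0.34.

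Radiation on the control diet was compared with no radiation, 3 mice against 3. miR-421 was at -0.93 ± 0.20, miR-466b-3-3p at -1.18 ± 0.25, miR-30a-3p at -0.98 ± 0.25, miR-26b# at 1.32 ± 0.32 and miR-503 at 0.68 ± 0.19, and none of them passed. miR-34a was at 0.06, from 2.31 ± 0.21 to 2.37 ± 0.11 (SD), and miR-150 at -0.05. miR-21 was at -0.84 ± 0.36. With limma, 0 of 296 assays were called, 30 had an unadjusted p under 0.05 and the smallest adjusted p was 0.149, for miR-421. No list held a called member, and in the miR-30 family and the ciliated markers 1 member each passed when adjusted over the list alone. Without mouse 4, 2 assays were called.

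Pooled over diets, radiation was compared with none in 6 mice against 6. The smallest p values were those of miR-466b-3-3p (-0.97 ± 0.19), miR-25 (1.83 ± 0.37), miR-455 by assay 002455A (-0.82 ± 0.20), miR-34c (1.60 ± 0.39) and miR-340-5p (0.84 ± 0.21). miR-34a was at -0.22 and miR-150 at -0.42. With limma, 0 assays were called, 50 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0957. The count was 19, all increases, with no normalization, 2 with undetected reactions set to 28, 2 without mice 2 and 11 and 2 without mouse 11.

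Irradiated flaxseed mice were compared with mice that had neither treatment, 3 against 3, and the values of both groups look like means of 2 readings. miR-150 fell by 1.76 ± 0.29 on the log2 scale, from 5.25 ± 0.62 to 3.50 ± 0.13 (SD), and was the 1 assay called (limma adjusted p = 0.0321), with 39 at an unadjusted p under 0.05. miR-1198 was at -0.91 ± 0.19, miR-503 at -0.92 ± 0.19, miR-34a at 0.77 ± 0.17, miR-342-3p at -0.93 ± 0.23 and miR-142-3p at -2.23, without a call. The call of miR-150 was lost in 16 of 29 alternatives, whose adjusted p ran from 0.00191 to 0.415, among them the fits without mouse 5, 7, 8, 9, 12, 13, 15 or 18, in each of which 0 assays were called, and the fit without mouse 17, in which 1 other assay was called. The count was 3 without mouse 2 and 2 without mouse 4. Unirradiated flaxseed mice were set against irradiated control mice, whose values both lack the 4th decimal, in a comparison chosen after the data were seen. There 41 assays were called, 20 higher and 21 lower, miR-34a rose by 1.22 and miR-503 fell by 0.97 on the log2 scale, while miR-150 was at -0.91 (limma adjusted p = 0.0666). That count of 41 was 20 without mouse 5, 17 without mouse 7, 9 without mouse 8, 6 without mouse 9, 23 without mouse 12, 20 without mouse 15, 20 without mouse 17 and 19 without mouse 18.

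The interaction asked whether radiation acted differently on the 2 diets. Its largest positive values were in miR-29c (7.55 ± 1.85), miR-25 (4.61 ± 0.73), miR-712 (3.72 ± 0.85), miR-193b (3.66 ± 0.93), miR-34c (3.62 ± 0.77) and miR-23b (3.52 ± 0.77), and miR-21 was at 2.98 ± 0.54. Its largest negative values were in miR-449b (-2.80 ± 0.61), miR-1903 (-2.42 ± 0.62), miR-26b# (-2.36 ± 0.45) and miR-184 (-2.05 ± 0.52). By limma, 25 assays were called, 14 positive and 11 negative, with 86 at an unadjusted p under 0.05, and 11 of the 14 positive ones also fell in unirradiated flaxseed mice. By list, 2 of 7 oxygen and stress and 2 of 8 fibrosis-linked microRNAs were positive, and 2 of 11 in the Dlk1-Dio3 locus were negative. Also positive were 1 of 10 p53-linked, 1 of 9 inflammation-linked, 2 of 11 in the miR-17 to miR-92 clusters, 1 of 3 in the miR-29 family, 1 of 7 in the miR-30 family and 1 of 2 endothelial markers, while of 4 ciliated markers miR-34c was positive and miR-449b negative. The positive member of the miR-30 family was miR-30a-3p. For miR-34a (-0.57) and miR-150 (-0.74) no difference between diets passed (adjusted p by limma = 0.145 and 0.238). The count was 0 when scaled to the control RNAs, 7 with the authors' normalized values, 12 without mouse 2, 0 without mouse 7, 0 without mouse 8, 15 without mouse 9, 10 without mouse 12, 2 without mouse 17 and 0 without mouse 18. The share of positive calls was 56%, against 70.6% with quantile normalization, 33.3% when scaled to the median assay and 95.8% with no normalization, with a median of all assays of -0.26, -0.21, -0.52 and 0.37.

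Some microRNAs were detected in all 3 mice of 1 group and in no mouse of another. miR-7, miR-194, miR-409-3p, miR-96 and, by 1 of its 2 assays, miR-351 were detected in all irradiated flaxseed and all unirradiated control mice and in no unirradiated flaxseed mouse. In the same way miR-382 was detected in all irradiated flaxseed mice and miR-1960 in all unirradiated control mice, and neither in an unirradiated flaxseed mouse. All of these but miR-1960 were read by pool A assays. Pool A assays detected in mice 11, 12 and 13 numbered 178, 181 and 175, against 190 to 194 in the other mice. Detection was set on the threshold cycle before scaling, so late pool A reactions, weighed below, stay open for them. The other assay of miR-351 was detected in all 12 mice, with a mean level of -2.58 in unirradiated control mice and -2.66 in unirradiated flaxseed mice. miR-339-3p was detected in irradiated flaxseed mice and in no irradiated control mouse. There were 6 such cases for radiation among flaxseed mice and 6 for flaxseed in unirradiated mice, which share the unirradiated flaxseed mice. For flaxseed in irradiated mice there was 1, and between the control diet groups 0. The most in any other split of the 6 mice of a comparison was 1. Over the 4 simple comparisons this made 13, with an assay found in more than 1 comparison counted each time, and 21 without mouse 12. Irradiated mice had 10.3 more detected assays than unirradiated mice (exact two-sided permutation p = 0.0628, 6 against 6), and 15.8 more at a Crt limit of 26 (exact permutation p = 0.00649). The difference was 7.67 at a limit of 30 and 6.83 with no limit (exact permutation p = 0.0996 for each). Without mouse 2, 4 or 5 the difference at the limit of 28 was 12.1, 12.5 or 12.1 (exact permutation p = 0.0303, 0.0173 and 0.0303), and it was smallest without mouse 13. At the limit of 28 flaxseed mice had -7.67 against control diet (exact permutation p = 0.188). The difference was 21.7 for radiation among flaxseed mice, -19 for flaxseed among unirradiated mice, 3.67 for flaxseed among irradiated mice and 2.67 for both treatments against neither, each with an exact permutation p of 0.1, the smallest that 3 against 3 can give, and -1 for radiation on the control diet (exact permutation p = 0.5).

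Effects were compared across the 296 assays, which are not independent replicates. The radiation effects in the control and flaxseed diets had a Pearson r of -0.18 and a Spearman rho of -0.35, and 136 of 400 splits of the mice gave an r as large. The flaxseed effects with and without radiation had an r of -0.07 and a rho of -0.02, with 320 of 400 splits as large. miR-34a was the 1 assay called higher in both comparisons of flaxseed with control diet, where 0.35 were expected if the calls were independent, and 0 assays were called lower in both by limma. Of the 15 calls in irradiated mice, 5 increases and 5 decreases were also called in the pooled comparison, which uses the same mice, among them miR-150, miR-503 and miR-34a.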

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

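The tests of the 3 patterns weighed here were all chosen only after the result was seen, while the counts of other splits were planned.

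The interaction term was called in 25 assays, where an effect of diet and the readings weighed below cannot be told apart. The named ones were miR-29c (7.55), miR-25 (4.61), miR-712 (3.72), miR-193b (3.66), miR-34c (3.62), miR-23b (3.52), miR-28 (3.42), miR-467a (3.14), miR-21 (2.98) and miR-126# (2.47) with positive values, and miR-449b (-2.80), miR-1903 (-2.42), miR-26b# (-2.36), miR-184 (-2.05), miR-136 (-1.73), miR-410 (-1.50), miR-672 (-1.46), miR-345-5p (-1.33), miR-503 (-1.31) and miR-345-3p (-1.26) with negative ones. Among the control RNAs, which entered no comparison, Y1 differed between flaxseed and control diet mice by 1.33 in pool A and 0.85 in pool B, and U87 by -0.55 in pool A (limma, adjusted p over the 10 control assays = 0.00814, 0.027 and 0.027). Over 5 scalings these ranged from 1.05 to 1.44, from 0.57 to 0.96 and from -0.83 to -0.44, so the scaling to the control RNAs rests on RNAs that moved apart.

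In unirradiated flaxseed mice, 19 of the 21 assays that fell were in primer pool A (90.5% against 61.1% of the tested assays). Lower transcription is argued against for the 5 members paired by name with an assay of the other arm, such as miR-29c and miR-21. Over these pairs the other arm of the hairpin showed a median of -10.3% of the fall. In that median miR-340-5p entered with each of its pairs, miR-340# (-22.4%) and miR-340 (-5.7%). Assays whose names are written otherwise, such as miR-423-3P and miR-24-2#, were not paired. Less RNA as a delay common to a whole mouse is removed by the global mean, and the 19 assays were chosen after it. That all 19 stayed called lower by limma when scaled to the control RNAs was thus close to fixed and decides nothing. All 19 also stayed called lower when scaled to the mean of each primer pool. This argues against a delay common to pool A as the whole cause. The 3.46 cycles by which they were later than the other pool A assays (3.8 against 0.34) decide nothing, as the 19 were chosen for being low. Less RNA as a part stays open: the 5 pool A control RNAs were later by 4.2%, -8.7% and 32.4% of the delay of the 19 assays in mice 11, 12 and 13, and by up to 51.2% with 2 standard errors in mouse 13, where under 50% was asked. Late single pool A reactions and a loss of these strands alone, from the diet, stay open too, since the pool A count (Fisher's exact two-sided p = 0.00426) is what showed the pattern and the other arm lies in pool B in 5 of the 6 pairs.

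The interaction calls follow the same split of the groups as the 4th decimal, which looks like single readings against means of 2 readings. Readings alone, with no effect of diet or radiation, are argued against for the 19 pool A falls, because irradiated control mice 7, 8 and 9, which share the format, showed a median of 23.2%, 11.9% and -4% of the fall. The levels of these mice were not in the difference that chose the 19. They entered the choice only through the spread of the shared fit, the detection filter and the global mean. For the interaction itself, readings alone would put the radiation difference in the control diet, sign turned, at about 0.5 of it, and the median ratio was 0.109 (0.015 to 0.496) for the 11 calls that also fell in unirradiated flaxseed mice and 0.493 (0.209 to 0.758) for the other 14, among them miR-503, miR-449b and miR-26b#. Neither ratio decides, because readings beside separate effects of diet and radiation can give any ratio, and the 11 were sorted by falls that enter it. For all 25, readings and an effect of diet on the radiation response cannot be told apart, because the split is the interaction itself.

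Over both radiation states miR-34a was higher and miR-150 lower with flaxseed, in a comparison balanced for the readings. Both calls held in 5 of 6 other scalings, and miR-34a lost its call with no normalization (0.72, limma adjusted p = 0.13, against 0.99 ± 0.12 and 0.00192), so a part of its difference from the scaling stays open. Fewer lymphoid cells in the flaxseed lungs may lower miR-150, and the rule first set to exclude this was met by miR-181a, which lay 2.87 standard errors above 50% of the fall of miR-150. That rule was set aside after the value was seen, since miR-181a is also abundant outside lymphocytes, and the other members left it undecided (miR-342-3p -0.58 ± 0.16, miR-155 -1.62 ± 1.67). A change of these microRNAs within cells of flaxseed mice stays open and was not tested.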

How the results depend on the processing

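Fits without mice 2 and 11 or without the 3 unirradiated flaxseed mice were chosen only after the result was seen, and all other alternatives were planned. Of 243 named results, 100 were calls, none reversed, and 5 calls held under every alternative: miR-150, miR-503 and miR-124a for pooled flaxseed, and miR-25 and miR-26b# for flaxseed in unirradiated mice. No alternative removes late single pool A reactions, which stay open for miR-124a and miR-25, both among the 19 pool A falls. Nor does any remove the split of the 4th decimal, which lies across the comparison in unirradiated mice. The other 95 lost their call in at least 1. Over single named values and alternatives, 5952 kept their side of the threshold, 701 lost a call and 90 gained one. The cause of the moves was not tested, except that fits without a mouse or group, fits of the compared groups alone and filters use fewer values.

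Calls for radiation among flaxseed mice (43) were 20 when scaled to the control RNAs, 65 with no Crt limit, 0 in a fit of these groups alone and 78 at an adjusted p under 0.10, and 9 to 49 without single mice. Those for flaxseed in unirradiated mice (36) were 60 when scaled to the median assay, 9 in a fit of these groups alone, 18 with array weights and 57 at 0.10, and 20 to 41 without single mice. Those for flaxseed in irradiated mice (15) were 4 when scaled to the control RNAs, 1 with no normalization, 48 in a fit of these groups alone, 72 with array weights, 32 without mice 2 and 11, 26 without the 3 unirradiated flaxseed mice, and 2 to 25 without single mice. For both treatments against neither (1) the count was 0 with quantile normalization, when scaled to the control RNAs or the median assay, with no normalization, within each pool, in a fit of these groups alone and without the 3 unirradiated flaxseed mice. It was 4 for assays detected in all 12 mice, 8 with array weights, 4 at 0.10, 13 without mice 2 and 11, and 0 to 3 without single mice.

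For radiation pooled (0) it was 19 with no normalization, 1 with the authors' values, 1 at a Crt limit of 26, 2 with undetected reactions set to 28, 2 at 0.10, 2 without mice 2 and 11, and 0 to 2 without single mice; in the control diet (0) it was 0 to 2. For flaxseed pooled (31) it was 19 with quantile normalization, 14 when scaled to the control RNAs, 16 with no normalization, 49 with array weights, 48 at 0.10, and 6 to 49 without single mice. For the interaction (25) it was 0 when scaled to the control RNAs, 7 with the authors' values, 16 at a limit of 30, 16 with no limit, 14 for assays detected in all 12 mice, 15 with undetected reactions set to 28, 60 at 0.10, and 0 to 31 without single mice. List shifts (0) were 3 with no normalization, 10 for assays detected in all 12 mice, and 0 to 4 without single mice (4 without mouse 11, 3 without mouse 13). Irradiated mice had 15.8 more detected assays at a limit of 26, 7.67 more at 30 and 6.83 more with no limit (exact permutation p = 0.00649, 0.0996 and 0.0996). The difference was 6.7 to 12.5 without single mice, smallest without mouse 13. For flaxseed this ran from -9.97 to -3.77, and the cases of an assay detected in 1 group alone, summed over comparisons, from 13 to 21. The r of radiation effects ran from -0.26 to -0.05 and that of flaxseed effects from -0.161 to 0.062, positive without mouse 2 (0.062), mouse 7 (0.039) or mouse 17 (0.036). Where a group was left with 2 mice, limma pooled the spread over groups.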

Other observations

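The counts of other splits were planned, and no test in this part was chosen after the result was seen.

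Markers of cell types with fewer than 3 tested members were set beside the others, flaxseed against control diet over both radiation states. miR-451, abundant in red blood cells, was at -0.60 ± 0.55 (SE). miR-126, a microRNA of endothelial cells, was at -0.10 ± 0.20 and its other arm miR-126# at -0.27 ± 0.32. miR-145 and miR-143, abundant in smooth muscle, were at 0.36 ± 0.13 and, by assay 002249A, 0.10 ± 0.12. miR-146a, which is raised by inflammatory signals, was at 0.04 ± 0.18, miR-210, which is raised by low oxygen, at 0.09 ± 0.16, and let-7b at -0.12 ± 0.19, and none of these was called by limma.

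The 12 mice were split in other ways to see how many calls chance gives. For flaxseed pooled over radiation, 1 of 100 splits gave as many calls as the real 31, the real split itself. The highest other gave 20, and the share under 0.05 argues against chance. For the interaction, 1 of 100 gave as many as the real 25, with 16 as the highest other. Those splits mixed all 12 mice over the 4 groups, so the separate effects of diet and radiation were broken up too. They argue against no difference between any of the groups. They cannot decide on chance in the interaction alone, or on the readings. For radiation pooled over diets, 100 of 100 splits gave as many as the real 0. Any split must give at least 0, so this share decides nothing. The highest other split gave 34. That split, looked at for its high count, kept all unirradiated flaxseed mice apart from all irradiated ones. It put control diet mice 2, 5 and 9 against mice 4, 7 and 8. The contrast of the 2 flaxseed groups, which that split holds, gave 43 calls in the fit of all 12 mice and 0 in a fit of these groups alone. A structure of the samples beyond that contrast was not tested.

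For the comparisons of 3 mice with 3, 10 splits are too few for a share under 0.05. For radiation on the control diet the share was also fixed, since any split gives at least the real 0. The real count and the highest other were 43 and 0 for radiation among flaxseed mice (1 of 10 splits as large), 36 and 6 for flaxseed in unirradiated mice (1 of 10), 15 and 0 for flaxseed in irradiated mice (1 of 10), 1 and 0 for both treatments against neither (1 of 10), and 0 and 0 for radiation on the control diet (10 of 10).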
